A study of Homo sapiens with 12 samples.

How the data were processed

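The samples were 12 RNA-seq libraries of SK-N-SH cells, a human neuroblastoma line, grown on substrates of 1, 8 or 30 kPa, with 4 libraries per stiffness. Per the submitters' processing notes, reads were aligned with HISAT2 to the human genome build GRCh38. The deposited table holds raw counts per gene and library, under Ensembl gene identifiers. The counting tool, the annotation release, the strand setting and any filter were not given in the sources used here. Without a stated strand setting, reads of a gene and of an antisense partner cannot be told apart. The labels number the libraries within each stiffness and do not say whether they came from separate cultures.

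The table held 60664 genes, of which 60463 were matched by identifier to the gene table used for names and 42028 had a symbol. Positions and gene types were taken from GENCODE v29, which is on GRCh38. Library totals ran from 1.43e+07 to 1.59e+07 counts at 1 kPa, from 1.50e+07 to 2.53e+07 at 8 kPa and from 2.39e+07 to 2.78e+07 at 30 kPa. The totals fell into 2 classes, with none between 1.59e+07 and 2.39e+07. The 5 shallow libraries were the 4 at 1 kPa and 8 kPa replicate 1, and the 7 deep libraries were the rest.

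Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with filterByExpr, which left 17960 genes holding at least 99.87% of the counts of every library. Library sizes were scaled by TMM, and all 12 libraries were fitted together with the stiffness as the only term. Groups were compared with edgeR's quasi-likelihood F-test, and p-values were adjusted over the tested genes by the Benjamini-Hochberg method with a threshold of 0.05. Every adjusted p of a single gene comes from that test unless another tool is named. Each standard error (SE) of a log2 fold change was taken as its size divided by the root of the F statistic. The biological coefficient of variation was 0.0966. Tests were made for each pair of stiffnesses, across all stiffnesses at once, and for the departure of 8 kPa from the mean of 1 and 30 kPa on the log2 scale. A second count took genes past the threshold with a change of at least 2-fold. Levels are given as CPM, counts scaled to the library total after TMM, with the standard deviation (SD) over the 4 libraries. P-values measure differences against the spread between libraries, which may be technical spread where libraries share a culture.

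Genes named in the text followed a rule. For each pair of stiffnesses these were the 5 highest and 5 lowest fold changes among genes past the threshold with a mean of at least 5 CPM, a symbol and no overlap between the libraries of the groups. Up to 3 members of each gene list with the smallest adjusted p were added, as were 13 genes in every comparison, of which 1 is not reported here (the others were YAP1, WWTR1, CCN1, CCN2, ANKRD1, PIEZO1, ACTA2, MYC, MYCN, ALK, VIM and MKI67). For the departure of 8 kPa, the 5 highest and 5 lowest genes were taken by the same rule. A gene outside the rule is named as chosen after its values were seen.

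A set of 28 gene lists was fixed before the data were examined, as were the tests, the naming rule and the alternatives except those named below as chosen later. They covered YAP/TAZ targets, SRF and actin contractility, focal adhesions and integrins, collagens and matrix glycoproteins, matrix crosslinking and proteolysis, mechanosensitive channels and sensors, and TGF-beta and BMP response. Cell state was covered by adrenergic and mesenchymal neuroblastoma genes, neuronal differentiation, and neural crest and Schwann precursor genes. Growth and metabolism were covered by G2/M, DNA replication, replication-dependent histones, ribosomal proteins, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, glycolysis and hypoxia, and cholesterol biosynthesis. Stress and signalling were covered by p53 targets, interferon response, NF-kB inflammatory genes, unfolded protein and ATF4 response, and immediate-early genes. Markers of fibroblasts, immune, epithelial and endothelial cells were included for contamination. Lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with adjustment over 84 tests. Camera was repeated with an estimated correlation, fry was run as another test, and members were also adjusted over each list alone.

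The edgeR, limma-voom and DESeq2 1.42.0 steps were tested on simulated counts for 8 kPa against 1 kPa with 17960 genes, of which 100 were changed by 1.5-fold and 100 by 2-fold. The edgeR step recovered 87% of the 1.5-fold and 99% of the 2-fold changes with 10 false calls. With limma-voom the shares were 86% and 99% with 8 false calls, and with DESeq2 90% and 99% with 25 false calls. Each gene was drawn on its own, without spread shared across genes or a shift between depth classes. These figures check the steps and do not give the error rate in the real libraries.

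Alternatives were median-ratio normalization, library size alone, no filter and a stricter low-count filter (at least 1 CPM in all libraries of a group), the replicate number as a block, 2 groups alone, limma-voom, DESeq2, and leaving out each library in turn. A term for the depth class, an offset that removes each library's trend on transcript length and GC content, thinning of all libraries to the smallest total, and an exact permutation test of list means were chosen after seeing the data. Length and GC content were known for 98.7% of tested genes. The overlap of the comparisons with 1 kPa was set beside 40 simulations of unchanged groups, with all 12 libraries drawn anew, and beside splits of the 1 kPa libraries. Other splits of the libraries were refitted to count how often they gave as many calls, with all 35 splits for pairs and 100 drawn splits for all 12 libraries. No library was left out of the fit.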

Results

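The series asks how the stiffness of the surface under neuroblastoma cells shapes their gene expression. SK-N-SH is a human neuroblastoma cell line that contains neuron-like cells and flat, substrate-adherent cells. Stiffness is given in kilopascals (kPa), a unit of elastic modulus, and a lower value means a softer surface. RNA was sequenced from 4 libraries each at 1, 8 and 30 kPa. Replicates 1 to 4 held 1.43e+07, 1.44e+07, 1.59e+07 and 1.55e+07 counts at 1 kPa, 1.50e+07, 2.51e+07, 2.53e+07 and 2.42e+07 at 8 kPa, and 2.39e+07, 2.40e+07, 2.78e+07 and 2.53e+07 at 30 kPa. All 1 kPa libraries were thus shallower than all 30 kPa libraries, and 8 kPa replicate 1 was as shallow as those at 1 kPa. Transcripts of the mitochondrial genome took 13.5% ± 1.59 of counts at 1 kPa, 10.7% ± 0.555 at 8 kPa and 12.4% ± 0.605 at 30 kPa (SD, n = 4 each). The correlation across genes of expression relative to the mean library with transcript length ran from 0.108 to 0.167 in the 1 kPa libraries, from -0.207 to -0.0773 at 8 kPa and from -0.159 to 0.125 at 30 kPa. On the first principal component, which held 27.5% of the variance, 1 kPa replicate 2 lay farthest out at -42.7.

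**Figure D1:**
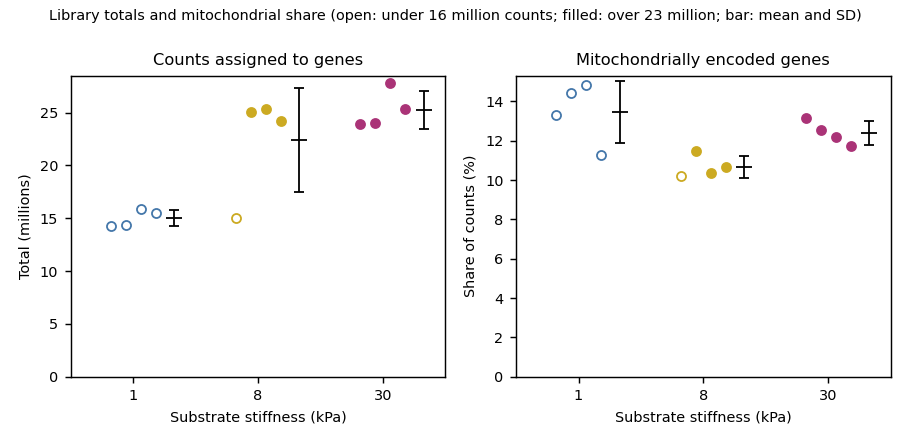
Total counts and share of counts on mitochondrially encoded genes for the 12 libraries, by stiffness, with shallow libraries set apart from deep ones. The 1 kPa libraries held 1.43e+07 to 1.59e+07 counts and the 30 kPa libraries 2.39e+07 to 2.78e+07.

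Cells on 8 kPa were compared with cells on 1 kPa to ask what changes when the softest surface is replaced by the middle one. DLGAP5, a mitotic spindle protein, went from 25.8 ± 3.24 CPM at 1 kPa to 40.7 ± 3.70 CPM at 8 kPa (SD, n = 4 each), a log2 fold change of 0.66 (SE 0.0954, adjusted p = 0.00521). Ribosomal protein RPL3 went from 562 ± 86.8 to 828 ± 59.3 CPM, a log2 fold change of 0.56 (SE 0.0975, adjusted p = 0.00756). The nuclear long noncoding RNA NEAT1, which builds paraspeckles, fell from 1750 ± 307 to 1016 ± 162 CPM, a log2 fold change of -0.78 (SE 0.13, adjusted p = 0.00692). These 3 calls held in all 12 fits that left out 1 library.

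Of 29 measured G2/M genes, which drive mitosis, 25 rose and 0 fell at 8 kPa, or 27 when adjusted over the list alone, with a median log2 fold change of 0.46. Among them KIF20A, a mitotic kinesin, rose by 0.59 and UBE2C, which helps destroy mitotic cyclins, by 0.60 on the log2 scale. The proliferation marker MKI67 rose by 0.43 (adjusted p = 0.0293), a call lost without 1 kPa replicate 3, 8 kPa replicate 1 or 8 kPa replicate 3 (highest adjusted p 0.0878). The camera test placed the list above other genes (adjusted p = 2.27e-21), but adjusted p = 0.512 with an estimated correlation. Of 30 DNA replication genes 14 rose and 0 fell, or 24 adjusted over the list alone, among them RRM2, RRM1 and TYMS, which supply deoxynucleotides, at 0.47, 0.34 and 0.38. The camera adjusted p was 4.67e-13, and adjusted p = 0.579 with an estimated correlation. Of 16 replication-dependent histone genes H2BC11, H2BC12 and H2AC6 rose (0.87, 0.47 and 0.24), or 6 adjusted over the list alone (camera adjusted p = 0.000392, and adjusted p = 0.555 with an estimated correlation). In 8 kPa replicate 1, which matched the 1 kPa libraries in depth, 27 of the 29 G2/M genes, 26 of the 30 replication genes and 14 of the 16 histone genes lay above all 4 of the 1 kPa libraries. Two-sided exact permutation tests of the list mean gave p = 0.0286, the smallest that 35 splits allow, for the G2/M and replication genes and for the ribosomal, nuclear oxidative phosphorylation, cholesterol and interferon lists. The exact p was 0.0571 for the histone, mitochondrially encoded and neural crest lists, 0.0857 for the neuronal and 0.143 for the adrenergic list. After adjustment no list in any comparison had an exact p under 0.2.

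Of 33 ribosomal protein genes 32 rose at 8 kPa and 0 fell, or all 33 adjusted over the list alone, with a median log2 fold change of 0.43. RPS3 and RPS9 rose by 0.52 and 0.47 (camera for the list, adjusted p = 2.23e-28; adjusted p = 0.512 with an estimated correlation). All 33 were above each 1 kPa library in the shallow 8 kPa library, a count that again rests on that 1 library. Of 31 nuclear-encoded genes of oxidative phosphorylation, which make up the respiratory chain, 19 rose and 0 fell, or 23 and 2 adjusted over the list alone, with a median of 0.22. The respiratory subunits NDUFB3, SDHB and ATP5F1C rose by 0.43, 0.32 and 0.29 (camera, adjusted p = 6.26e-10; adjusted p = 0.555 with an estimated correlation). The 13 protein genes of the mitochondrial genome went the other way, with 7 lower and 0 higher, or 13 lower adjusted over the list alone, and a median of -0.38 (camera, adjusted p = 2.17e-08; adjusted p = 0.555 with an estimated correlation). MT-ND4L fell from 3745 ± 720 to 2492 ± 360 CPM and MT-CYB from 10190 ± 1460 to 7341 ± 706 CPM, and both calls were lost without 8 kPa replicate 1 or 3 (highest adjusted p 0.0658, for MT-CYB without replicate 3). Among glycolysis and hypoxia genes 8 of 30 rose and 1 fell, or 8 and 3 adjusted over the list alone. The glycolytic enzymes PGAM1 and PGK1 rose by 0.35 and 0.23, and the list as a whole did not pass (camera, adjusted p = 0.177). The cholesterol enzymes ACAT2 and FDFT1 rose by 0.38 and 0.22, and 22 of the 24 members did not pass, with 2 adjusted over the list alone (camera, adjusted p = 0.0219; adjusted p = 0.555 with an estimated correlation; 0.0725 without 8 kPa replicate 2 and 0.103 with the depth class as a term).

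Some neural genes were higher at 8 kPa, while most members of the neural lists did not pass. Of 26 adrenergic neuroblastoma genes, which mark the sympathetic neuron-like state, 6 rose and 0 fell, or 9 adjusted over the list alone. Among them STMN2, a microtubule regulator of growing neurites, rose by 0.72 (camera for the list, adjusted p = 5.73e-05; adjusted p = 0.684 with an estimated correlation). Of 25 neuronal differentiation genes 6 rose and 0 fell, or 10 adjusted over the list alone, among them the growth cone protein GAP43 at 0.66 and the neurofilament genes NEFM and INA at 0.70 and 0.78 (camera, adjusted p = 5.73e-05; adjusted p = 0.672 with an estimated correlation). STMN2, GAP43, NEFM and INA each lost their call in 3 to 6 of the 12 fits that left out 1 library, in every case without 8 kPa replicate 1 and without 8 kPa replicate 3 (adjusted p without replicate 1 of 0.114 for NEFM and 0.106 for INA). Among 10 neural crest and Schwann precursor genes S100B, MSX2 and SOX2 rose (1.14, 0.61 and 0.77), or 3 adjusted over the list alone (camera, adjusted p = 0.282). These calls were lost in 4, 5 and 8 of the 12 fits that left out 1 library (highest adjusted p 0.117, for SOX2). SOX2 in 8 kPa replicate 4 (3.438 CPM) lay within the range of the 1 kPa libraries (3.229 to 4.402 CPM), and S100B was at most 2.231 CPM in any library. The proliferation factor MYC rose by 0.61, while MYCN, at 0.20, and ALK, at 0.06, did not pass. The list of mesenchymal neuroblastoma genes did not pass (camera, adjusted p = 0.145), with ID1 and TWIST2 higher and IRF1 lower out of 25, the same counts adjusted over the list alone.

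Of 22 YAP/TAZ target genes ARHGEF17 alone passed, at -0.26, also when adjusted over the list alone, and the median was -0.23. CCN1 and CCN2, secreted matrix proteins that YAP and TAZ switch on, had log2 fold changes of -0.64 (adjusted p = 0.183) and -0.72 (adjusted p = 0.137), and without 1 kPa replicate 4 these were -0.91 (adjusted p = 0.0148) and -0.98 (adjusted p = 0.018). Both also passed with no filter (0.0469 and 0.0219). YAP1 did not pass (-0.15, adjusted p = 0.0705). It did with a stricter filter (0.0435), with DESeq2 (0.0283), with the replicate number as a block (0.0487) and without 1 kPa replicate 4 (0.0498) or 8 kPa replicate 4 (0.0446). WWTR1 (-0.18, adjusted p = 0.337), the YAP target ANKRD1 (-0.44, 0.411), the stretch-gated channel PIEZO1 (-0.09, 0.784), smooth muscle actin ACTA2 (-0.06, 0.673) and vimentin VIM (-0.01, 0.967) did not pass either. The YAP/TAZ list stood lower by camera (adjusted p = 0.0251; adjusted p = 0.763 with an estimated correlation), and adjusted p was 0.332, 0.0924 and 0.128 without 1 kPa replicate 2, 1 kPa replicate 3 and 8 kPa replicate 1. Among 28 collagen and matrix glycoprotein genes SPARC and COL4A1 fell, with 0 adjusted over the list alone (camera, adjusted p = 0.0339; adjusted p = 0.709 with an estimated correlation), and the list call was lost without 1 kPa replicate 2 (0.109), 1 kPa replicate 3 (0.143) or 8 kPa replicate 1 (0.119) and with the length and GC offset (0.0896). Of 29 matrix crosslinking and proteolysis genes 0 passed by edgeR, over all genes or the list alone (camera, adjusted p = 0.0219; adjusted p = 0.763 with an estimated correlation), and the list call was lost without 1 kPa replicate 2 (0.348) or 8 kPa replicate 1 (0.0949). The integrins ITGAV and ITGA11 fell among 29 focal adhesion genes (adjusted p = 0.552 for the list), and the actin genes MYH10 and TPM4 rose among 22 SRF genes (0.669), in both cases also adjusted over the list alone. Among 24 mechanosensors the lamin LMNB2 rose by 0.43, with 3 higher and 4 lower, or 5 and 6 adjusted over the list alone (0.836).

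Among signalling lists, 4 interferon response genes fell and 1 rose out of 29, the same adjusted over the list alone, led by the RNA sensor DDX60 at -0.36 and STAT2 at -0.49 (camera, adjusted p = 0.0786; fry, adjusted p = 0.0194). VCAM1 and CSF1 fell among 24 NF-kB genes (camera, adjusted p = 0.166), SLC7A11 and SLC3A2, the chains of a cystine transporter, among 29 ATF4 and unfolded protein genes (0.836), with 2 adjusted over the list alone in each. FOSB and ZFP36 fell and MYC rose among 27 immediate-early genes (0.669), also adjusted over the list alone. The BMP targets ID1 and ID2 rose among 24 TGF-beta and BMP genes, with 4 higher and 1 lower, or 4 and 3 adjusted over the list alone (0.848). CCNG1 rose among 26 p53 targets, with 0 adjusted over the list alone (0.83). None of the 7 fibroblast, 2 immune, 5 epithelial and 4 endothelial marker genes measured passed edgeR's test over all genes or over the list alone (camera, adjusted p = 0.401, 0.996, 0.977 and 0.95). The median and mean of the SRF, unfolded protein, epithelial and endothelial lists differed in sign in this comparison, as did those of the TGF-beta, p53, glycolysis and neural crest lists at 30 against 1 kPa.

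The largest changes by the naming rule were in other genes. UBE2QL1, a ubiquitin-conjugating enzyme-like gene (ENSG00000215218, GRCh38 chromosome 5, 6448623 to 6494909), rose from 15.5 ± 4.08 to 28.8 ± 5.57 CPM (log2 fold change 0.89, SE 0.17, adjusted p = 0.00962). PRKCB, a protein kinase C, rose by 1.03 (SE 0.235, adjusted p = 0.0152) and GNAZ, a G protein subunit, by 0.98 (SE 0.208, adjusted p = 0.0123), and both calls were lost without 8 kPa replicate 3 (adjusted p = 0.0563 and 0.0513). SEMA4A, a semaphorin, fell from 12.7 ± 3.13 to 7.08 ± 0.659 CPM (log2 fold change -0.84), and GSTM2, a glutathione transferase, from 18.9 ± 2.87 to 11.2 ± 2.02 CPM (-0.74). The pseudogenes RPL39P3 (1.32) and RPL7AP6 (0.90) rose too, but share reads with their parent genes and are uncertain. TSIX (-0.96) and THBS3-AS1 (-0.70) lie antisense to other genes, whose reads cannot be told apart from theirs here.

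In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 2472 of 17960 genes between 8 and 1 kPa, 1467 higher and 1005 lower at 8 kPa, with a median size of 0.34 on the log2 scale, and 60 of them changed at least 2-fold. The count was 534 without 8 kPa replicate 3, 771 without 8 kPa replicate 1, 1096, 1414 and 1575 without 1 kPa replicates 2, 3 and 1, and 1068 in a fit of the 8 libraries alone. Of the 69 genes past the threshold that the naming rule took, 29 kept their call without each library in turn. With the depth class as a term, edgeR called 0 genes, while 4299 had an unadjusted p under 0.05. The median change of the 2472 genes was then 0.41 in the called direction and its median SE 0.131, against 0.0819 without the term. With the term the 8 kPa level rests on replicate 1, the single shallow library at 8 kPa. The 60 calls of at least 2-fold became 8, 33, 127, 23, 37 and 145 without 8 kPa replicates 3, 1 and 4 and 1 kPa replicates 2, 3 and 4, 0 with the depth class as a term (432 at an unadjusted p under 0.05), 19 with a stricter low-count filter, 9 with DESeq2 and 21 in the 8 libraries alone.

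Cells on 30 kPa were compared with cells on 8 kPa to ask what the stiffest surface adds to the middle one. No single gene passed edgeR's test, and values for genes that did not pass are given as such. CCN1 stood at 88.5 ± 21.5 CPM at 8 kPa and 174 ± 34.3 CPM at 30 kPa (SD, n = 4 each; log2 fold change 0.97, SE 0.314, adjusted p = 0.164), and CCN2 at 63.2 ± 18.6 and 110 ± 23.9 CPM (0.79, SE 0.314, adjusted p = 0.22). ALK, a receptor tyrosine kinase mutated in some neuroblastomas, stood at 9.20 ± 1.40 and 15.5 ± 2.59 CPM (0.75, SE 0.128, adjusted p = 0.0848). ALK passed without 1 kPa replicate 2 (adjusted p = 0.0329), 1 kPa replicate 4 (0.0456), 8 kPa replicate 4 (0.0206) or 30 kPa replicate 4 (0.0272), with DESeq2 (0.000166), with no filter (0.000251) and in the 8 libraries alone (0.0491). It also passed with the replicate number as a block (0.0148), a pairing that the labels do not state. WWTR1, which encodes the co-activator TAZ, had a log2 fold change of -0.43 (adjusted p = 0.15), and passed without 8 kPa replicate 4 (0.0368), with DESeq2 (0.0357) and with no filter (0.0134). CCN1 passed with no filter (0.00629) and in the 8 libraries alone (0.0399), and CCN2 with no filter (0.0347). Further from the threshold were PIEZO1 (0.46, adjusted p = 0.218), VIM (-0.23, 0.397), MYC (0.20, 0.428), YAP1 (-0.07, 0.475), ACTA2 (0.07, 0.666), MKI67 (-0.05, 0.843), ANKRD1 (0.13, 0.865) and MYCN (0.04, 0.945).

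YAP/TAZ target genes leaned up at 30 kPa, with positive fold changes in 20 of 22 and a median of 0.19 (camera, adjusted p = 1.46e-05; adjusted p = 0.667 with an estimated correlation). When adjusted over the list alone, 5 members passed, AMOTL2 (0.83), LATS2 (0.56), ARHGEF17 (0.22), CCN1 and PTPN14 (0.49), named after their values were seen apart from CCN1. LATS2, AMOTL2 and PTPN14 are themselves restrainers of YAP. The 7 fibroblast markers had a median of 0.25 in the same comparison, with 0 passing edgeR's test over all genes or the list alone (camera, adjusted p = 0.111). The exact p of the list mean was 0.0571 for them and for the YAP/TAZ list. Matrix crosslinking and proteolysis genes leaned the same way, with 23 of 29 positive and a median of 0.19 (camera, adjusted p = 0.000443; adjusted p = 0.672 with an estimated correlation). The 4 that passed when adjusted over the list alone, chosen after their values were seen, were the proteases PLAU (0.70), ADAMTS1 (0.40) and MMP9 (0.91) and the protease inhibitor TIMP2 (0.20). Immediate-early genes, which answer growth factors and stress within minutes, leaned down with a median of -0.24 (camera, adjusted p = 0.000398; adjusted p = 0.512 with an estimated correlation). Adjusted over the list alone, 4 of 27 were lower, EGR1 (-0.98), EGR2 (-1.47), FOS (-0.96) and FOSB (-0.99), again chosen after their values were seen. The exact p of the list mean was 0.0286 for this list and for the 4 endothelial markers, whose 30 kPa libraries all lay below the 8 kPa libraries. Of these markers 0 passed over all genes and 1 was lower adjusted over the list alone, PECAM1 (-1.75), named after its values were seen (camera for the list, adjusted p = 0.609).

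Genes of the ribosome and the respiratory chain leaned back toward the 1 kPa level. This comparison shares the 8 kPa libraries with that of 8 against 1 kPa, so the 2 are not independent. The lean was not set against what unchanged groups would give. All 33 ribosomal protein genes had negative fold changes (median -0.18; camera, adjusted p = 6.26e-10; adjusted p = 0.672 with an estimated correlation), as did 28 of 31 nuclear oxidative phosphorylation genes (median -0.13; adjusted p = 4.21e-07; adjusted p = 0.583 with an estimated correlation). Adjusted over the list alone, 0 ribosomal and 2 oxidative phosphorylation genes were lower, the latter NDUFB3 (-0.28) and NDUFS1 (-0.18), both chosen after their values were seen. Mitochondrially encoded genes leaned up (median 0.27; camera, adjusted p = 1.94e-05; adjusted p = 0.667 with an estimated correlation), with 0 members adjusted over the list alone. Weaker camera calls placed the neuronal differentiation list (adjusted p = 0.0301; adjusted p = 0.763 with an estimated correlation), the cholesterol list (0.0369; adjusted p = 0.555 with an estimated correlation), the unfolded protein list (0.0162; adjusted p = 0.693 with an estimated correlation) and the histone list (0.0329; adjusted p = 0.693 with an estimated correlation) lower at 30 kPa. Each of these 4 was lost without some libraries. The neuronal call was lost without 8 kPa replicates 1 (0.201) and 2 (0.0912) and 30 kPa replicates 3 (0.0811) and 4 (0.145), with a stricter filter (0.0855), with the depth class as a term (0.203) and with the replicate number as a block (0.0641). The cholesterol call was lost without 8 kPa replicate 2 (0.173) and 30 kPa replicates 1 (0.0624), 3 (0.0598) and 4 (0.0844), with a stricter filter (0.0697), with the replicate number as a block (0.0891) and after thinning (0.0915). The unfolded protein call was lost without 8 kPa replicate 2 (0.333) or 30 kPa replicate 1 (0.0817), and the histone call without 8 kPa replicates 1 (0.209) and 3 (0.0585) or 30 kPa replicate 4 (0.131), with the depth class as a term (0.205), with the length and GC offset (0.138) and after thinning (0.13). G2/M genes showed a median of 0.00 and did not pass (camera, adjusted p = 0.848).

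The edgeR test called 0 genes between 30 and 8 kPa, with a smallest adjusted p of 0.0807, while 3218 genes had an unadjusted p under 0.05. DESeq2 called 435 genes and limma-voom 0. The count was 1026 without 8 kPa replicate 4, 187 and 21 without 1 kPa replicates 2 and 4, 1 without 30 kPa replicate 4, 330 with no filter, 40 with the replicate number as a block and 61 in the 8 libraries alone. List calls by camera need care in all comparisons, since 22 of 100 splits of the 12 libraries (the true one included) gave at least the 33 list calls found, and 0 lists passed with an estimated correlation or with adjusted exact permutation tests of the list mean. Fry kept 6 of the 33 calls and lost 27. At 8 against 1 kPa it kept the G2/M, ribosomal, nuclear oxidative phosphorylation and cholesterol lists (fry, adjusted p = 0.0194 each). At 30 against 1 kPa it kept the G2/M (0.0194) and immediate-early (0.0316) lists. At 30 against 8 kPa the smallest adjusted p by fry was 0.0547.

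Cells on 30 kPa were compared with cells on 1 kPa to contrast the stiffest with the softest surface. Mitotic genes and ALK were higher at 30 kPa, and 4 of 27 immediate-early genes and some matrix and adhesion genes were lower. ALK (ENSG00000171094, GRCh38 chromosome 2, 29192774 to 29921566) rose from 8.79 ± 0.425 to 15.5 ± 2.59 CPM (SD, n = 4 each), a log2 fold change of 0.82 (SE 0.133, adjusted p = 0.00919). COL15A1, a basement membrane collagen (ENSG00000204291, chromosome 9, 98943179 to 99070792), fell from 14.2 ± 2.52 to 5.81 ± 0.353 CPM, a log2 fold change of -1.29 (SE 0.153, adjusted p = 0.00317). FOSB, an AP-1 transcription factor, fell from 2.30 ± 0.882 to 0.585 ± 0.0383 CPM (-1.98, SE 0.269, adjusted p = 0.00487).

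Of the 29 G2/M genes 18 rose and 0 fell at 30 kPa, or 28 adjusted over the list alone, with a median of 0.49 (camera, adjusted p = 4.14e-34; adjusted p = 0.512 with an estimated correlation). HMMR, a spindle protein, went from 35.2 ± 2.89 to 53.6 ± 7.38 CPM (log2 fold change 0.61), and TOP2A, a topoisomerase of dividing cells, rose by 0.56, a call lost without 30 kPa replicate 3 (adjusted p = 0.0601). An exact permutation test of the list mean gave p = 0.0286, against 0.0857 for the DNA replication list and 0.0571 for the ribosomal and histone lists. UHRF1, RRM2, MCM2 and RRM1 rose among 30 DNA replication genes, RRM1 named after its values were seen, or 18 adjusted over the list alone (camera, adjusted p = 4.41e-14; adjusted p = 0.555 with an estimated correlation). RPS3 rose among 33 ribosomal protein genes, or 22 adjusted over the list alone (camera, adjusted p = 1.99e-14; adjusted p = 0.621 with an estimated correlation), and H2BC11 among 16 histone genes, or 1 adjusted over the list alone. The calls of UHRF1, RRM2, MCM2, RPS3 and H2BC11 were lost in 4, 7, 8, 9 and 5 of the 12 fits that left out 1 library. The histone list call (camera, adjusted p = 0.0229; adjusted p = 0.684 with an estimated correlation) was lost without 1 kPa replicate 4 (0.2) or 30 kPa replicate 1 (0.0574). No member of the nuclear oxidative phosphorylation or the mitochondrially encoded list passed, over all genes or over the list alone. By camera these lists stood higher (adjusted p = 0.0065; adjusted p = 0.761 with an estimated correlation) and lower (0.00871; adjusted p = 0.761 with an estimated correlation). The former call was lost without 1 kPa replicate 2 (0.154) or 30 kPa replicate 4 (0.097), and the latter without 1 kPa replicate 2 (0.0535) or 3 (0.204).

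Of 26 adrenergic genes 4 rose and 0 fell, ALK, SIX3 (0.73) and PHOX2A (0.52, named after its values were seen) among the former, or 8 higher and 1 lower adjusted over the list alone (camera, adjusted p = 1.08e-05; adjusted p = 0.672 with an estimated correlation). The ALK call held in all 12 fits that left out 1 library, while that of SIX3 was lost in 10 (highest adjusted p 0.127). Among 25 mesenchymal genes WWTR1 (-0.62), YAP1 (-0.22) and PRRX1 (-0.35), a mesenchymal transcription factor, fell and 0 rose, or 5 lower adjusted over the list alone. The calls of WWTR1, YAP1 and PRRX1 were lost in 4, 9 and 1 of the 12 fits that left out 1 library. The camera call of the mesenchymal list (adjusted p = 0.0126; adjusted p = 0.512 with an estimated correlation) was lost without 1 kPa replicate 3 (0.0526) or 30 kPa replicate 1 (0.0624). WWTR1 went from 134 ± 27.5 to 87.8 ± 4.96 CPM, while its target CCN1 did not pass (0.34, adjusted p = 0.612) and 0 of 22 YAP/TAZ targets passed edgeR's test over all genes or the list alone (camera, adjusted p = 0.402). Neuronal differentiation genes were split, with CNTN1 (0.75) and SNAP25 (0.31, named after its values were seen) higher and the secretory granule genes SCG2 (-0.67) and VGF (-0.59) lower, or 4 and 2 adjusted over the list alone. The neuronal list stood higher by camera (adjusted p = 0.0065; adjusted p = 0.761 with an estimated correlation), a call lost without 1 kPa replicate 2 (0.225). MYC rose by 0.81 (adjusted p = 0.0125), lost without 30 kPa replicate 3 (0.0601). MKI67 (0.38, adjusted p = 0.0998) did not pass. It did with no filter (0.00978), with DESeq2 (0.0376) and without 1 kPa replicate 4 (0.0416). PIEZO1 (0.37, adjusted p = 0.293), VIM (-0.24, 0.368), MYCN (0.24, 0.659), ANKRD1 (-0.31, 0.684), ACTA2 (0.01, 0.949) and CCN2 (0.06, 0.941) did not pass. Of these VIM did with the replicate number as a block (0.0311).

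Of 27 immediate-early genes FOSB, ZFP36, EGR2 and EGR1 fell and MYC rose, or 8 and 1 adjusted over the list alone. EGR2 went from 4.12 ± 1.10 to 1.03 ± 0.399 CPM (log2 fold change -2.01) and ZFP36, which destabilises inflammatory messages, from 15.6 ± 2.00 to 8.70 ± 1.29 CPM (-0.84), and EGR1 (-0.95) was named after its values were seen. The list stood lower by camera (adjusted p = 5.32e-05; adjusted p = 0.512 with an estimated correlation), and its mean differed by an exact permutation test (p = 0.0286). VCAM1, an adhesion molecule, fell from 95.9 ± 14.8 to 55.9 ± 9.00 CPM, and ITGA10, a collagen-binding integrin, from 28.4 ± 5.74 to 15.3 ± 1.71 CPM. COL3A1 (-0.52), SPARC (-0.32) and COL4A1 (-0.27) fell among 28 collagen and matrix glycoprotein genes, also adjusted over the list alone (camera, adjusted p = 0.123). These 3 calls were lost in 2, 6 and 8 of the 12 fits that left out 1 library. LMNA, a lamin of the nuclear envelope, fell by 0.51 on the log2 scale while LMNB2 rose by 0.40, and both calls were lost without 30 kPa replicate 3 among others. SLC7A11 (-0.57) and the stress factor DDIT3 (-0.38) fell among 29 unfolded protein and ATF4 genes, or 6 adjusted over the list alone (camera, adjusted p = 0.00826; adjusted p = 0.673 with an estimated correlation), with the list call lost without 30 kPa replicate 1 (0.0624). The DDIT3 call was lost in 11 of the 12 fits that left out 1 library (highest adjusted p 0.144), and that of SLC7A11 in 3. IFITM1 (-1.16) and DDX60 (-0.26) fell among 29 interferon genes (camera, adjusted p = 0.106; fry, adjusted p = 0.0316). Their own calls were lost in 5 and 10 of the 12 fits that left out 1 library. Of the 4 endothelial markers 0 passed over all genes and PECAM1, named after its values were seen, was lower when adjusted over the list alone (-1.75, adjusted p over all genes 0.0521). The endothelial list did not pass by camera (adjusted p = 0.531), while its mean was below the lowest 1 kPa library in all 4 libraries at 30 kPa (exact p = 0.0286). The remaining lists did not pass by camera.

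Among the largest changes by the naming rule, the metalloprotease TLL1 (-1.52), the adhesion molecule CEACAM1 (-1.47) and the neuronal protease inhibitor SERPINI1 (-1.44) fell. All 3 calls were lost without 30 kPa replicate 3 (adjusted p = 0.0601 each), and that of SERPINI1 also without 30 kPa replicate 4. UBE2QL1 (0.88) and the receptor PROKR2 (0.84) rose. These calls were lost without 3 and 7 of the 12 libraries (highest adjusted p 0.0623 and 0.1). The pseudogenes RPL39P3 (1.30) and RPS27P3 (1.14) are uncertain, since they share reads with their parent genes, and RMEL3 (-1.49) is an antisense noncoding RNA, whose reads cannot be told apart from those of its partner without strand.

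**Figure D2:**
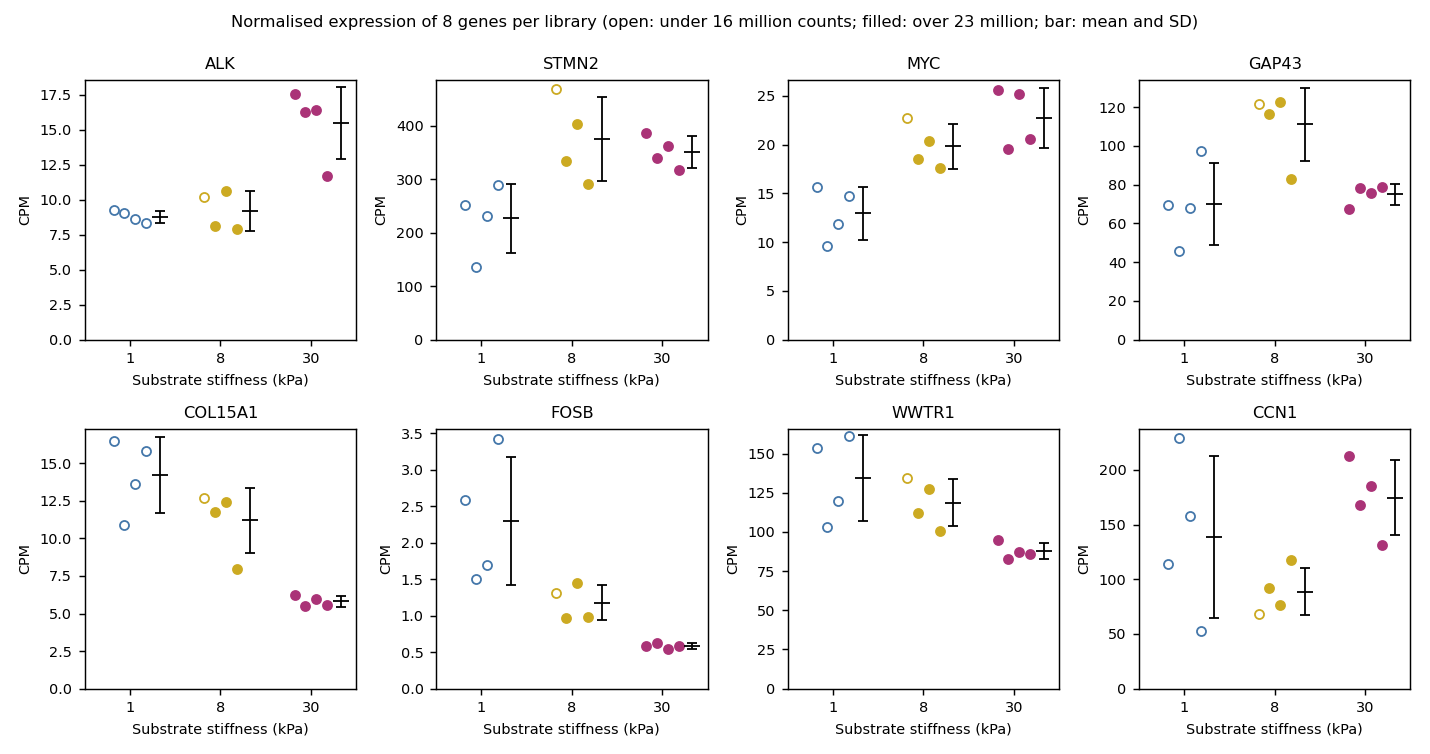
Expression in CPM of ALK, STMN2, MYC, GAP43, COL15A1, FOSB, WWTR1 and CCN1 in each library by stiffness, with open points for shallow and filled points for deep libraries and bars for the mean and SD of 4 libraries. ALK had a mean of 8.79, 9.20 and 15.5 CPM and COL15A1 of 14.2, 11.2 and 5.81 CPM at 1, 8 and 30 kPa.

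In all, edgeR's test called 437 genes between 30 and 1 kPa, 198 higher and 239 lower at 30 kPa, with 37 changed at least 2-fold. The count was 50, 135, 217 and 225 without 30 kPa replicates 3, 4, 2 and 1, 153 and 156 without 1 kPa replicates 3 and 1, and 237 and 676 without 8 kPa replicates 3 and 4. It was 1035 with DESeq2, 875 with no filter, 974 with the replicate number as a block and 263 with library size alone. All 1 kPa libraries were shallow and all 30 kPa libraries deep, so depth class and stiffness cannot be told apart in this comparison except through 8 kPa replicate 1. With the depth class as a term edgeR called 0 genes, while 1763 had an unadjusted p under 0.05, and the median change of the 437 genes was 0.44 in the called direction with a median SE of 0.176, against 0.0903 without the term. Of the 51 genes past the threshold that the naming rule took, 9 kept their call without each library, among them ALK, COL15A1, ITGA10, HMMR, VCAM1, FOSB and ZFP36. The 37 calls of at least 2-fold became 7, 14, 20 and 23 without 30 kPa replicates 3, 4, 2 and 1, 16 and 72 without 1 kPa replicates 1 and 2, 71 with no filter and 0 with the depth class as a term (302 at an unadjusted p under 0.05).

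**Figure D3:**
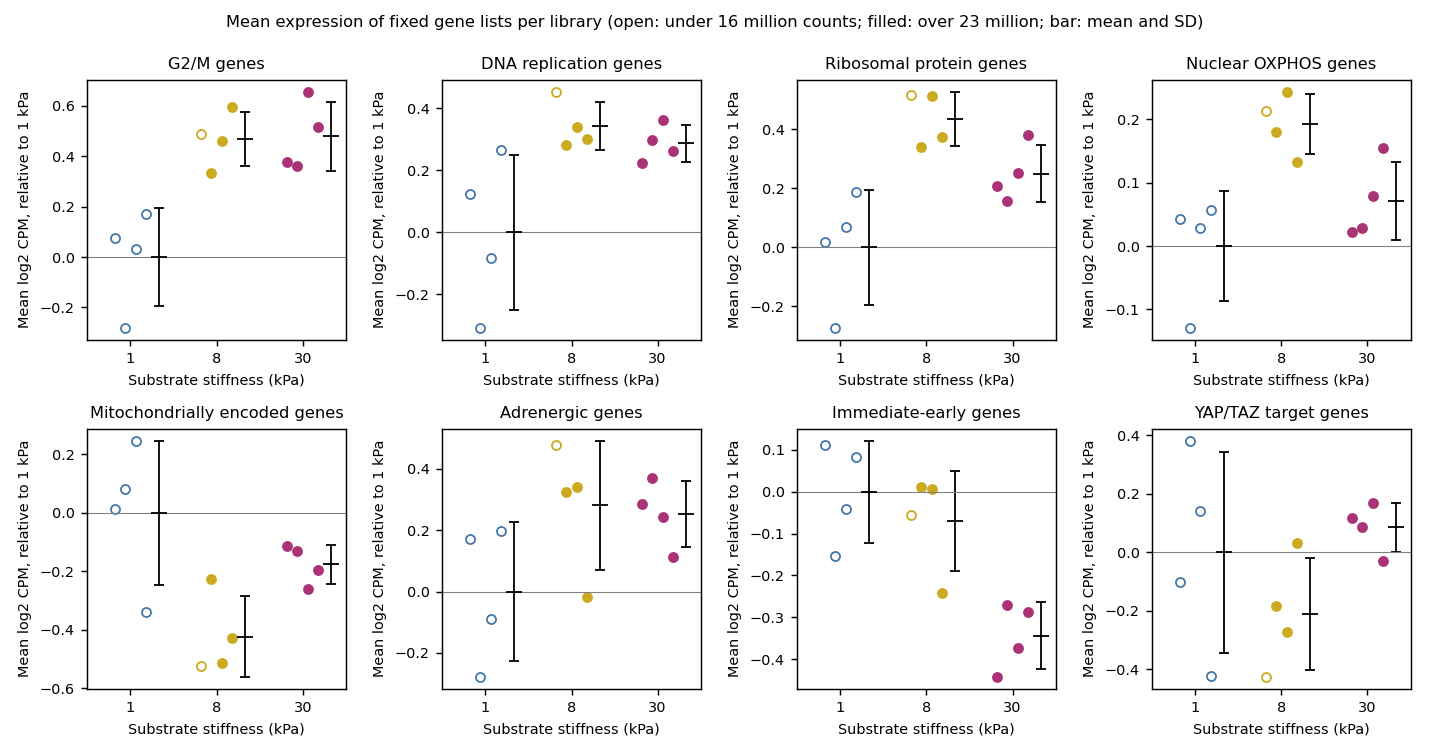
Mean log2 CPM of the members of 8 gene lists in each library, relative to the mean of the 1 kPa libraries, with open points for shallow and filled points for deep libraries and bars for the mean and SD of 4 libraries. G2/M scores ran from -0.28 to 0.17 at 1 kPa, from 0.33 to 0.60 at 8 kPa and from 0.36 to 0.66 at 30 kPa.

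The level at 8 kPa was also set against the mean of 1 and 30 kPa, to ask where the middle stiffness departs from the midpoint of the extremes. A gene that changes between 1 and 8 kPa and then stays level can also pass, so a call need not mean a peak or dip at 8 kPa. No list test was made for this contrast. Of 17960 genes 1272 passed. Of the 1272 genes 556 had all 8 kPa libraries above or below all those at 1 and 30 kPa, against 759 of all 17960 genes. Of ribosomal protein genes 26 of 33 were higher at 8 kPa than that mean and 0 lower, or all 33 adjusted over the list alone. Of nuclear oxidative phosphorylation genes 12 of 31 were higher and 0 lower, or 21 adjusted over the list alone. Of the glycolysis and hypoxia list 6 of 30 were higher, or 9 adjusted over the list alone. MT-ND3, MT-CYB and MT-ND4L, named after their values were seen, were lower among 13 mitochondrially encoded genes, or 12 adjusted over the list alone. Of single genes NEAT1 stood lower, at -0.67 on the log2 scale (SE 0.115, adjusted p = 0.0231), TMEM91 at -0.58, FAM111A, a protease that restricts viral replication, at -0.55 and CES4A at -0.55. TAGLN3, a neuronal actin-binding protein, stood higher by 0.51, LSM3, an RNA-processing protein, by 0.50 and PRSS3, a trypsinogen, by 0.54. RPL7P9 and RPL7AP6 (pseudogenes) and TSIX (antisense) were also named by the rule and are uncertain for the reasons given. The edgeR test called 1272 genes in this contrast, 794 higher and 478 lower at 8 kPa and 1268 with the depth class as a term. It called 0 genes without 8 kPa replicate 1, 8 kPa replicate 3 or 30 kPa replicate 1, 1 without 30 kPa replicate 2, 176 without 8 kPa replicate 2, 262 without 30 kPa replicate 3, 458 and 543 without 1 kPa replicates 3 and 1, and 2614 and 2870 without 1 kPa replicate 4 and 8 kPa replicate 4. In the full fit 4938 genes had an unadjusted p under 0.05, DESeq2 called 2259, and all 10 named genes lost their call without at least 1 library.

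Across the 3 stiffnesses, edgeR called 1646 genes. The count was 230, 380 and 936 without 8 kPa replicates 3, 1 and 2, 390 and 437 without 1 kPa replicates 1 and 3, 737, 906 and 1062 without 30 kPa replicates 3, 1 and 2, and 2546 and 3234 without 1 kPa replicate 4 and 8 kPa replicate 4. It was 0 with the depth class as a term, where 4030 genes had an unadjusted p under 0.05, and 3058 with DESeq2.

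The comparisons with 1 kPa overlapped. Of the 437 genes called at 30 against 1 kPa, 272 (62.2%) were also called at 8 against 1 kPa in the same direction, 165 higher and 107 lower, and 0 in the opposite direction. Independent lists of these sizes would share 16.2 higher and 13.4 lower genes, a figure that leaves out the shared 1 kPa libraries. The covariance of the log2 fold changes was 0.0518, against 0.0208 in 40 simulations of unchanged groups, a difference of 0.0311. The simulations drew all 12 libraries, the 1 kPa ones included, from 1 mean and 1 spread per gene, each gene on its own. They leave out any spread that the real 1 kPa libraries share across genes, so the difference cannot separate that from a shared change. Correlations across genes, which are not independent replicates, were 0.643 in the data and 0.569 in the simulations. With the 1 kPa libraries split between the comparisons the overlap ran from 0 to 55 with a mean of 15.5. In the split with 55, independent lists would share 40.9. In the others the overlaps were 12, 0, 20, 4 and 2, where independent lists would share 2.25, 0.00156, 1.1, 0.138 and 0.00479. Over the splits the correlations were 0.0444 to 0.407 and the covariances 0.0058 to 0.0391. The overlap was 31, 77, 132 and 148 without 30 kPa replicates 3, 4, 2 and 1, 75, 95, 172 and 448 without 1 kPa replicates 3, 1, 2 and 4, and 91, 145 and 168 without 8 kPa replicates 3, 1 and 2. It was 0 with the depth class as a term, which left 0 genes in either comparison.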

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

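The tests of length and GC content and of thinning on the counts of called genes, and the test of the depth class for 8 against 1 kPa, were chosen after the results were seen, as were the conditions below that a single shallow library decides nothing and that the 30 kPa position leave the range of the deep 8 kPa libraries, and the count of splits that could overlap. Within each group of 4 libraries, a library was set apart where its gap to the nearest other library, divided by the range of the group, passed Dixon's criterion. This happened in 23 of 426 groups (5.4%), and chance sets apart about 1 in 20. Of the 23 cases 8 fell on 8 kPa replicate 4 and 4 on 1 kPa replicate 2. The library 8 kPa replicate 4 was lowest of its group for SOX2 (ratio 0.948), EGR2 (0.914), GAP43 (0.868), MSX2 (0.861), COL15A1 (0.838) and H2BC12 (0.837), and highest for CSF1 (0.866) and the mechanosensor list mean (0.831). The library 1 kPa replicate 2 was lowest for the nuclear oxidative phosphorylation list mean (0.843), its member NDUFB3 (0.845) and IFITM1 (0.84), and highest for ARHGEF17 (0.868). The library 8 kPa replicate 1 was lowest of its group in total counts (0.893) and for CES4A (0.838), and 1 kPa replicate 4 was lowest for CES4A (0.86). SOX2 was highest in 1 kPa replicate 1 (0.928), and TPM4 in 8 kPa replicate 3 (0.86). Of the 30 kPa libraries replicate 1 was lowest for the glycolysis and hypoxia list mean (0.896) and ID2 (0.876), replicate 2 was lowest for H2BC12 (0.916) and highest for ACAT2 (0.832), and replicate 3 was highest for TOP2A (0.838) and HMMR (0.833).

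Other splits of the same libraries were counted to see how often as many calls arose without the true grouping. For pairs 1 of 35 is the smallest share possible, and these tests were not adjusted for their number. In fits of 8 libraries, the true split of 8 and 1 kPa was 1 of 35 to give as many calls, with 1068 against 0 for the highest other split. At 2-fold or more the counts were 21 against 0. The true split of 30 and 1 kPa was likewise 1 of 35, with 351 against 1, and 36 against 1 at 2-fold or more. For 30 against 8 kPa, 2 of 35 splits gave at least the 61 calls of the true one, and 2 gave at least its 6 calls of 2-fold or more, so chance cannot be excluded. The other split, which exchanges 8 kPa replicate 4 with 30 kPa replicate 2, gave 774 and 77 calls, several times those of the true one, which points to a structure of the samples. The log2 CPM of 8 kPa replicate 4 correlated with those of 8 kPa replicates 1 to 3 at 0.9876, 0.9898 and 0.9912. With 30 kPa replicates 1 to 4 the values were 0.9929, 0.9907, 0.9946 and 0.9946. For 30 kPa replicate 2 they were 0.9937, 0.9929 and 0.9929 with its own group and 0.9877, 0.9935, 0.9904 and 0.9907 with 8 kPa replicates 1 to 4. What structure lies behind the 774 calls was not tested, nor was an exchange of these labels. Among 100 drawn splits of the 12 libraries, the true one alone (1 of 100) reached its counts across the stiffnesses (1646 against 505) and for the departure of 8 kPa (1272 against 181). The departure count still fell to 0 without certain single libraries, as given above. For the overlap of the comparisons with 1 kPa the counts were 272 against 0 (1 of 100), but 0 of the 99 other splits called genes in both comparisons, so none could overlap and this decides nothing. For the gene lists 22 of 100 splits gave at least the 33 camera calls of the true one, with up to 41, so chance cannot be excluded for their number.

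The 2472 differences between 8 and 1 kPa, the ribosomal protein genes among them, could come from transcript length or GC content, from sequencing depth or its batch, or from the surface itself. With the length and GC trends removed 83.1% of the calls were kept in the same direction and the ribosomal median stayed at 0.372, and after thinning to equal depth 72.9% were kept, which argues against length, GC content and depth as the whole cause. If the depth class or its batch were the whole cause, the 30 kPa libraries, all deep, would lie at least as far from 1 kPa as the 8 kPa libraries, and on genes chosen by the 8 kPa difference itself their median position was 0.548 (quartiles 0.359 and 0.756) between the 1 kPa mean at 0 and the 8 kPa mean at 1. On genes called without them the deep 8 kPa replicates 2, 3 and 4 lay at 0.771, 1.09 and 0.506 and the single shallow replicate 1 at 1.17, so 0.548 is within the range of the deep ones, and the depth class or its batch and the stiffness cannot be told apart. With the depth class term no call remained, as the median SE rose from 0.0819 to 0.131, while the median change went from 0.34 to 0.41. Depth class varies within a stiffness only at 8 kPa, so with the term the 8 kPa level rests on replicate 1. That library helped choose the genes, so the kept median change cannot speak for or against the depth class.

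The 437 differences between 30 and 1 kPa could likewise come from length or GC content, from depth, from a batch that follows the depth class, or from the surface. With the trends removed 84.2% of the calls were kept, and after thinning 66.1%, which argues against those as the whole cause. Over the 437 genes the deep 8 kPa libraries exceeded the shallow one by a median share of -0.0314 of the difference between 30 and 1 kPa, against -0.141 to 0.0979 for each deep 8 kPa library in its place. The value lies within the bound written before the test for another cause than depth class, but that bound was wrong for this design, which has a single shallow library outside 1 kPa, so the depth class or its batch and the stiffness cannot be told apart here. With the depth class term no call remained, as the median SE rose from 0.0903 to 0.176, with the median change at 0.44 both without and with it. The term is set by the gap between 8 kPa replicate 1 and the other 8 kPa libraries alone, so the kept median change decides nothing about the depth class.

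The YAP/TAZ target list, which leaned up at 30 against 8 kPa with a median of 0.19, could reflect transcript length or GC content, a single library, or a response to the surface. With the length and GC trends removed the median was 0.162, which argues against that bias as the whole cause. The lowest median over the fits that left out 1 library was 0.144, without 8 kPa replicate 1, which argues against a single library. Between 30 and 1 kPa the list was not called (median 0.05; camera, adjusted p = 0.402; exact permutation of the list mean, p = 0.657). The list means at 1 kPa ran from -0.422 to 0.382, and the group mean was lowest at 8 kPa. The values thus show no rise from the softest to the stiffest surface. A response to stiffness remains a hypothesis, since the list was not called with an estimated correlation (adjusted p = 0.667) and splits at random gave as many list calls. A larger share of fibroblast-like cells was not tested and stays open as well, with a fibroblast marker median of 0.25.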

How the results depend on the processing

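The depth class term, the length and GC offset, the thinning and the exact permutation of list means were chosen after the results were seen. No named gene or list past the threshold, in the fit reported or under the alternative, changed direction. Changes of sign in results past the threshold in neither were not counted. For the changes below the cause was not tested, beyond the larger SE that the depth class term brings. With the depth class as a term edgeR called 0 genes for 8 against 1 kPa (0 of 2-fold or more), 0 for 30 against 1 kPa (0 of 2-fold or more), 0 across the stiffnesses and 0 in the overlap, where unadjusted p was under 0.05 for 4299, 1763 and 4030 genes. In fits of 2 groups alone the counts were 1068 for 8 against 1 kPa (21 of 2-fold or more) and 61 for 30 against 8 kPa (6). DESeq2 gave 9 of 2-fold or more for 8 against 1 kPa, 435 for 30 against 8 kPa (6), 1035 for 30 against 1 kPa, 3058 across the stiffnesses, 2259 for the departure of 8 kPa and 647 in the overlap. With no filter the counts were 330 for 30 against 8 kPa (34) and 875 for 30 against 1 kPa (71), with a stricter filter 19 of 2-fold or more for 8 against 1 kPa, with library size alone 263 for 30 against 1 kPa, and after thinning 823 for the departure. The camera calls of 33 became 8 with fry, 0 with an estimated correlation and 0 with exact permutation. The 8 by fry were 6 of the 33 and 2 of the interferon list, which camera had not called. The overlap averaged 15.5 with the 1 kPa libraries split. Leaving out 1 library gave 534 to 3563 for 8 against 1 kPa (8 to 145 of 2-fold or more), 0 to 1026 for 30 against 8 kPa (0 to 83), 50 to 676 for 30 against 1 kPa (7 to 72), 230 to 3234 across the stiffnesses, 0 to 2870 for the departure, 31 to 448 for the overlap and 28 to 35 list calls. The lowest counts for 8 against 1 kPa and across came without 8 kPa replicate 3, those for 30 against 1 kPa and the overlap without 30 kPa replicate 3, and the highest for 30 against 8 kPa and the departure without 8 kPa replicate 4. Replicate numbers were not taken to pair the libraries, since the labels state no pairing, but the values point to a partial one. Deviations from the group means of the 12 same-number pairs correlated at -0.13 to 0.37, with 6 over 0.1. Of the 12 libraries 5 correlated best with their own number in both other groups. Replicate 2 did so at every stiffness (0.24, 0.18 and 0.37). Its NF-kB list mean was the highest of each group, at 0.585, 0.553 and 0.538 for 1, 8 and 30 kPa. The fit reported leaves such shared spread in the error. A gene that did not pass there may therefore pass with the block, as VIM did at 30 against 1 kPa. With the replicate number as a block the counts were 40 for 30 against 8 kPa (4 of 2-fold or more), 974 for 30 against 1 kPa (56), 2626 across, 2096 for the departure and 617 in the overlap. Under the other alternatives counts stayed within 1.5 times of those reported. Of results for single named genes past the threshold, 206 lost their call and 1211 kept it over the alternatives, and 443 lost and 1117 kept it when 1 library was left out.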

Other observations

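The proteasome and lysosome lists used here were written after FLCN, GPNMB, PSMB5, PSMB6 and PSMD8 had been singled out from their values, and the condition that 0.25 of a list's members pass singly was added after the list results were seen. FLCN, which restrains the lysosomal regulators TFEB and TFE3, fell from 41.4 ± 3.45 CPM at 1 kPa to 25.8 ± 2.50 CPM at 8 kPa (SD, n = 4 each; log2 fold change -0.68, SE 0.0854, adjusted p = 0.00521), and stood at 33.4 ± 2.95 CPM at 30 kPa (-0.31 against 1 kPa, adjusted p = 0.0662). GPNMB, a lysosomal membrane glycoprotein and TFEB/TFE3 target, fell at 8 kPa (-0.62, adjusted p = 0.00521) and at 30 kPa (-0.58, adjusted p = 0.00596) against 1 kPa. A lower output of lysosomal and TFEB/TFE3 target genes may be behind these falls. In a list of 37 such genes without FLCN and GPNMB, 11 fell and 0 rose at 8 against 1 kPa, while at 30 against 1 kPa 0 passed edgeR's test over all genes and 6 were lower when adjusted over the list alone. The list stood lower by camera in both comparisons (adjusted p = 1.42e-05 and 0.000133), but not with an estimated correlation (adjusted p = 0.256 and 0.265), nor by exact permutation of the list mean (p = 0.0571 and 0.0857). The outcome written down before the test, a lower list by camera in both comparisons, was thus met, and the hypothesis is left open because of the added condition: 0 of 37 members passed at 30 against 1 kPa. At 30 against 8 kPa camera gave an adjusted p of 0.0916.

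PSMB5 and PSMB6, catalytic subunits of the proteasome, rose at 8 against 1 kPa (0.35 each, adjusted p = 0.00521), as did the regulatory subunit PSMD8 (0.34, adjusted p = 0.00656). A rise of proteasome genes as a group is a candidate explanation. Of 28 further subunits 10 rose and PSMA2 fell, or 20 and 2 adjusted over the list alone, with a median log2 fold change of 0.15 and of 0.13 after the length and GC trends were removed. The list stood higher by camera (adjusted p = 2.31e-06), with adjusted p = 0.256 with an estimated correlation, and its mean differed by an exact permutation test (p = 0.0286, the smallest that 35 splits allow). The values go with the hypothesis at 8 kPa, both as written before the test and with the added condition. The further subunits were tested in the same libraries that had singled out PSMB5, PSMB6 and PSMD8. The result is therefore not independent of the values that prompted the hypothesis. At 30 against 8 kPa 26 of the 28 had negative fold changes and 0 passed edgeR's test, or 1 lower adjusted over the list alone (median -0.11; camera, adjusted p = 1.88e-06; adjusted p = 0.256 with an estimated correlation). At 30 against 1 kPa 0 of the 28 passed edgeR's test, over all genes or the list alone, and camera gave an adjusted p of 0.153.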
